A study of Mus musculus with 2 samples.

How the data were processed

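The samples were 2 libraries of CD45+ cells, selected with beads from CT-2A tumours 14 days after intracranial implant, from wildtype and Glut5 (Slc2a5) KO mice, with 16000 cells loaded each. The design text of the record says knockdown where the sample labels say KO, and the labels are followed here. The sample titles speak of a mouse in the singular, yet both libraries held cells with Y-linked UMIs alone and cells with Xist alone, which does not match 1 animal. How many animals were pooled, their sex and the deleted exons are not given in the sources used here. The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization, per the file headers. The libraries were made with a 10x 5' v2 kit, per the labels' protocols. Reads were processed with Cell Ranger 3.1.0 and mm10, per the submitters' processing notes, while the matrix header names version 7.0.1, per the file headers. Whether intron reads were counted, and the annotation release, are not given in the sources used here. Both matrices hold the same genes.

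Depth over all barcodes was 116105873 UMIs in 11495 wildtype barcodes (median 8662 UMIs and 2598 genes per barcode) and 96851696 UMIs in 12165 Glut5 KO barcodes (median 6498 and 2157). Median mitochondrial shares were 0.498% and 0.441%. Barcodes with under 300 genes (2 wildtype and 26 Glut5 KO) or at least 10% mitochondrial UMIs (22 and 39) were removed. Doublets were scored in each library with Scrublet at an expected rate of 0.08.

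The doublet rule was changed after its result was seen. The rule as first written took the automatic threshold in each library, and the top 8% of scores where that threshold marked under 0.5%. The automatic threshold marked 2 wildtype barcodes (0.0174%) and 3491 Glut5 KO barcodes (28.7%), so the written rule would have treated the libraries unequally. The top 8% was removed in both instead (918 and 947 barcodes), and the rule as first written was run as an alternative. The kept 10555 wildtype cells had 100092751 UMIs (median 8118 UMIs and 2490 genes), and the kept 11165 Glut5 KO cells had 85985291 (median 6363 and 2118).

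Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were reduced to 30 principal components, without Slc2a5, immunoglobulin and T cell receptor variable genes, or mitochondrial, ribosomal and sex-linked genes. Cells of both libraries were clustered together, with no batch correction, by the Leiden method at resolution 1, on 20 neighbours, with seed 0. A cluster was named after a class when at least 3 of the class's markers were among its top 30 genes and that class led in its top 10 and top 30. Failing that, it was named when the class's relative marker level was at least 1.5 times the next class's. Genes were ranked by fold with 10 CPM added, among genes in at least 25% of the cluster's cells. Markers under 20 CPM in every cluster were left out. Monocyte, macrophage and border-associated macrophage markers counted as 1 class, called monocyte/macrophage. Of 33 clusters, 28 were named. Names end in -like because they rest on transcripts alone.

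Mixed cells were cells of T, NK, B or plasma clusters with at least 100 UMIs per 10000 from C1qa, C1qb, C1qc, Lyz2 and Apoe (for T and NK clusters also Cd74, H2-Aa, H2-Ab1 and H2-Eb1). They were taken out of their class. That limit was set after seeing the data, and doublets between other classes were not sought beyond Scrublet.

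Within each of the 7 classes with at least 200 cells in both libraries, counts were summed per library and divided by the total UMIs of the class, in CPM. The log2 ratio of Glut5 KO over wildtype was taken with 0.5 added to each count. With 1 library per genotype there was no test and no p-value. Intervals are exact 95% Poisson intervals for levels, Clopper-Pearson intervals for shares and conditional exact binomial intervals for ratios. They cover counting error alone. A level with 0 UMIs is given a floor of 3 counts over the class.

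Named genes were, before the data were examined, set as the 12 highest and 12 lowest log2 ratios in microglia-like cells, and 6 at each end in other classes. They needed at least 100 UMIs over both libraries and at least 50 CPM in 1 library, with mitochondrial, ribosomal, sex-linked, haemoglobin, predicted, immunoglobulin and T cell receptor genes and markers of other classes left out. The rule also named Slc2a5 everywhere and, for each list described, the 2 highest and 2 lowest members with at least 100 UMIs, plus members printed to show a list's range. Some members that this rule names are not reported here. Slc2a1, Ctla4, Cd74, Cxcl10, Csf1r and genes outside these rules were picked after their values were seen.

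The 27 gene lists, also set beforehand, needed 5 members with at least 20 UMIs. A list's value is the median log2 ratio of these members, with an interval from 1000 Poisson redraws of the counts and a percentile among 10000 random lists matched on 20 expression bins. Members at least 1.5-fold apart were counted by size alone. Lists are described one by one where the median is at least 1.2-fold from 0 and the percentile is under 2.5 or over 97.5, a rule set after seeing the data. The immunoglobulin list could be measured in microglia-like and monocyte/macrophage-like cells alone. A member was called far below another class where its level in both libraries was under 5% of that in the highest named class.

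Shares of cells with a UMI of a gene were taken after thinning each cell to 1000 UMIs and leaving shallower cells out, and again without thinning. Gene positions (GRCm38) were found for 26652 of 32245 symbols. Around Slc2a5, genes with at least 100 UMIs and at least 2-fold apart were counted within 30 Mb. Cells were called male by Y-linked UMIs without Xist, and female by Xist without Y-linked UMIs.

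The method was tested on simulated data, in which microglia-like counts were given known changes. Genes changed 1.5-fold had a median log2 ratio of 0.51 (true 0.53) and genes changed 2-fold 0.92 (true 0.94), with 95% and 100% of intervals holding the true value. In T cell-like cells the same changes gave 0.59 (true 0.57) and 1.00 (true 0.99), with 92.5% and 97.5%. The simulated class sums were Poisson draws, the error that the intervals assume, so this share was close to fixed in advance. Spread between cells, animals or libraries was not simulated, and the intervals do not cover it.

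The alternatives set beforehand were mitochondrial limits of 5% and 20%, at least 1000 genes per cell, doublets kept, Leiden resolutions of 0.5 and 2, each library clustered on its own, shares of immune classes alone, ratios scaled to a median of 0, the mean of per-cell CPM, thinned cells, list members with at least 100 UMIs or with no minimum, 5 added to each count, lists without members far below another class, shares without thinning, and all deposited barcodes. Alternatives chosen after seeing the data were the doublet rule as first written, mixed cells kept, female or male cells alone, shallow clusters left out, clusters weighted equally and lists without genes within 30 Mb of Slc2a5. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5 (with its Scrublet), anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.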

Results

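The immune cells of CT-2A tumours, a mouse glioma line grown in the brain, were profiled by droplet single-cell RNA sequencing in wildtype mice and in mice without Glut5, the fructose transporter encoded by Slc2a5. Tumours were taken 14 days after the implant, and leukocytes were pulled out with beads against CD45. There was 1 library per genotype, so no difference below has a replicate check or a p-value. Every difference is between these 2 libraries, and the genotype cannot be told apart from the batch of the library. The wildtype library held 11495 barcodes with 116105873 UMIs (unique transcript tags). The Glut5 KO library held 12165 barcodes with 96851696 UMIs. After filtering, 10555 wildtype and 11165 Glut5 KO cells were kept, with medians of 8118 and 6363 UMIs per cell. Brackets give exact 95% intervals that cover counting error only.

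The first question was whether the fructose transporter was lost, and which cells had it in the wildtype tumour. Slc2a5 (ENSMUSG00000028976, chromosome 4, 150119344 to 150144168, GRCm38) had 384 UMIs over all wildtype barcodes and 1 over all Glut5 KO barcodes. In the wildtype library it was mostly a transcript of microglia, the resident macrophages of the brain. Microglia-like cells held 82.9% of the Slc2a5 UMIs of kept wildtype cells, with 291 UMIs in 219 cells. Their level was 19.4 CPM (counts per 1e6 UMIs) [17.3 to 21.8] in wildtype, against 0 UMIs in Glut5 KO, with an upper bound of 0.321 CPM.

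Monocyte/macrophage-like cells had far less of the transporter. This class, named by monocyte, macrophage and border-associated macrophage markers together, had 10 wildtype UMIs (0.173 CPM) and 0 in Glut5 KO. Clusters that could not be named had 43 UMIs (15.7 CPM) in wildtype and 0 in Glut5 KO. Among them, cluster 19 held 151 wildtype and 42 Glut5 KO cells (share ratio 0.263 [0.182 to 0.372]). It was led by cell division genes such as Plk1 and by Il1a and Hcar2, which also lead microglia-like cluster 4. With every cell thinned to 1000 UMIs, 2.29% of wildtype microglia-like cells had an Slc2a5 UMI (1969 cells, 256 shallower cells left out, median 4232 UMIs), and 9.84% did without thinning. In Glut5 KO the thinned share was 0 of 1577 cells (460 left out, median 2599 UMIs), with an upper bound of 0.234%. Migratory dendritic cell-like cells, taken as background, gave 0.366% of 273 wildtype cells (median 4728 UMIs) and 0 of 217 Glut5 KO cells (median 4963 UMIs). The reads come from transcript starts, so a transcript that keeps its first exons would still be counted.

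**Figure D1:**
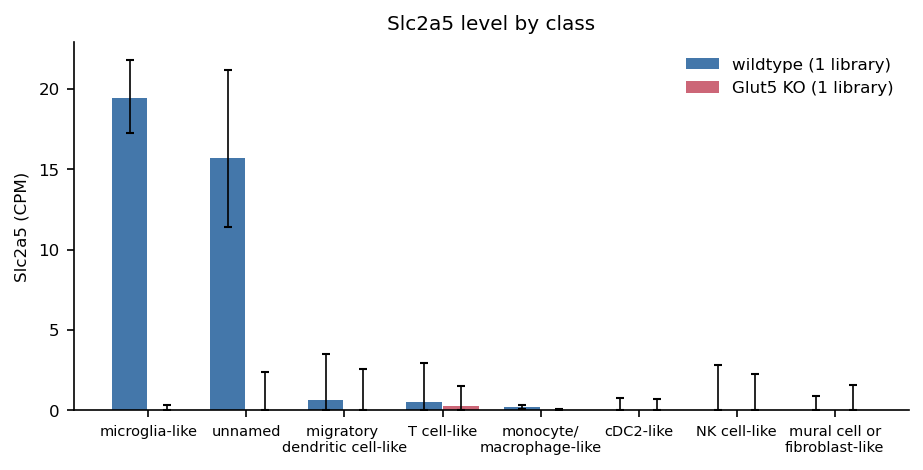
Slc2a5 in CPM (UMIs of the gene scaled to the class total) by cell class in the wildtype and Glut5 KO libraries, with exact Poisson intervals. Wildtype microglia-like cells stand at 19.4 CPM and their Glut5 KO counterparts at 0.

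The next question was which immune cells each tumour held. Lymphocytes made up more of the Glut5 KO suspension, and the main phagocytes made up less. T cell-like cells were 3.29% of wildtype cells (347) and 6.89% of Glut5 KO cells (769), a ratio of 2.10 [1.84 to 2.39]. That is a log2 ratio of 1.07, which fell to 0.68 when mixed cells, described below, were kept in their class. B cell-like cells, which make antibodies once they mature, were 17 against 265, or 0.161% against 2.37% (ratio 14.7 [9.03 to 25.7]). Plasma cell-like cells, the antibody secretors, were 4 against 122, or 0.0379% against 1.09%.

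Other classes with a higher share in Glut5 KO were plasmacytoid dendritic cell-like cells, the main makers of type I interferon, at 1.15% and 2.40% (ratio 2.09 [1.68 to 2.62]), and neutrophil-like cells, at 0.161% and 0.9404%. Mast cell or basophil-like cells, with 15 and 44 cells, stood at 0.142% and 0.394%. Monocyte/macrophage-like cells were 52.9% of wildtype and 46.0% of Glut5 KO cells (ratio 0.870 [0.838 to 0.904]). Microglia-like cells were 21.1% and 18.2% (ratio 0.865 [0.815 to 0.920]), but among male cells alone their log2 share ratio was 0.18. The antigen-presenting cDC1-like cells, 1.85% and 1.41%, and migratory dendritic cell-like cells, 2.68% and 2.13%, were also lower in Glut5 KO, while in female cells alone their log2 ratios were 0.54 and 0.02. The shares of cDC2-like cells (5.70% and 5.75%) and NK cell-like cells (2.77% and 2.71%), which kill stressed cells, did not differ beyond counting error over all cells. In female cells alone their log2 ratios were 0.54 [0.21 to 0.88] and 1.06 [0.48 to 1.70], and in male cells −0.15 and −0.46.

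Shares are of cells left after CD45 bead selection, and the Glut5 KO library was the shallower. Mixed cells, with transcripts of more than 1 class, were left out of the classes at a limit chosen after seeing the data, and made up 4.05% of wildtype and 5.11% of Glut5 KO cells, though with the doublet rule as first written their log2 share ratio was −1.17.

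**Figure D2:**
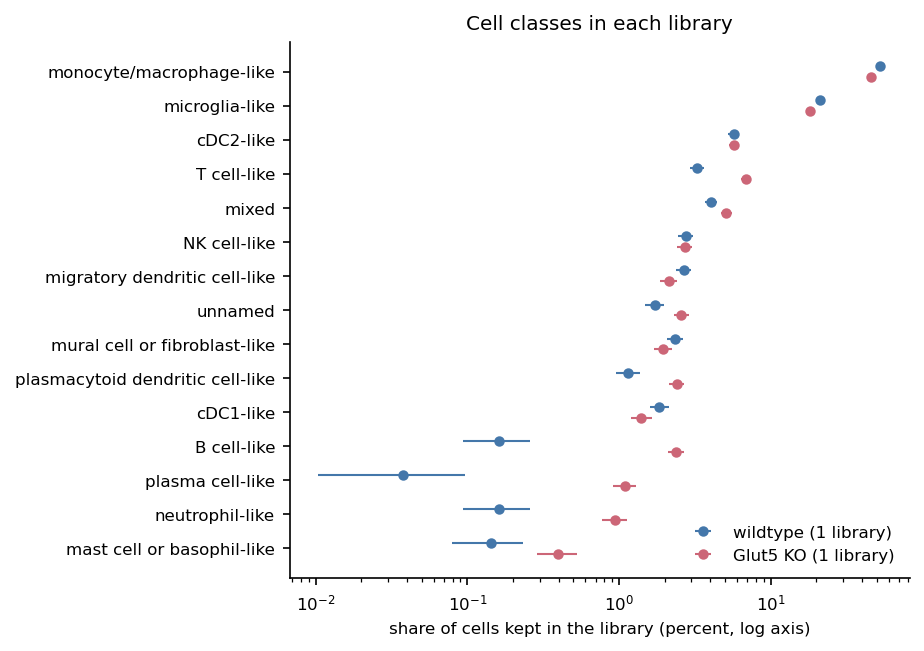
Share of kept cells (%) in each named class in the wildtype and Glut5 KO libraries, with exact Clopper-Pearson intervals. T cell-like cells stand at 3.29% and 6.89%, and monocyte/macrophage-like cells at 52.9% and 46.0%.

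Among T cell-like cells, transcripts linked to regulatory T cells, the T cells that restrain other immune cells, were found in more cells of the Glut5 KO library. With cells thinned to 1000 UMIs, Foxp3, the master regulator of regulatory T cells, was in 2.44% of 287 wildtype cells [0.986 to 4.96] and 5.93% of 641 Glut5 KO cells [4.23 to 8.05]. These intervals overlap, so for Foxp3 the difference is not clear of counting error. Ikzf2, a transcription factor that stabilises them but also leads the shallow cluster 12, was in 13.6% and 29.2%. Ctla4, an inhibitory receptor, was in 23.7% and 38.5%. The CD8 coreceptor gene Cd8a was in 14.98% and 14.7%, and the checkpoint receptor gene Pdcd1 in 28.6% and 28.7%.

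Without thinning the shares were 9.51% and 12.5% for Foxp3, 37.5% and 49.4% for Ikzf2, and 45.8% and 57.2% for Ctla4. Thinning left out 60 wildtype and 128 Glut5 KO T cell-like cells, whose classes had medians of 3233 and 2703 UMIs. No thinned migratory dendritic cell-like cell of either library (273 and 217 cells, medians 4728 and 4963 UMIs) had Foxp3, Ctla4 or Ifng. Their background shares were 0.366% and 1.38% for Ikzf2, 1.10% and 1.38% for Cd8a, and 4.396% and 3.23% for Pdcd1. Different clusters led the T cell-like class in each library. Cluster 10, led by Cd8a and Ifng, held 55.0% of wildtype and 36.0% of Glut5 KO T cell-like cells. The shallow cluster 12 held 28.2% and 42.7%, and cluster 18, led by Ctla4 and Foxp3, held 7.78% and 13.3%. These shares leave out mixed cells, and clusters lost them unequally. Cluster 9, also named T cell-like, lost 302 of 314 wildtype and 287 of 294 Glut5 KO cells. Cluster 18 lost 41 of 68 and 103 of 205, and cluster 10 lost 32 of 223 and 44 of 321.

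Microglia-like cells, the cells that lost Slc2a5, were compared gene by gene to ask what else differed in them. Cell cycle genes were lower in Glut5 KO microglia-like cells, with a median log2 ratio of −0.76 [−0.84 to −0.67]. The share of thinned cells with Mki67, a proliferation marker gene, ran the other way, at 1.63% and 2.09%, so no order was read from it. Of the 32 measured members, 23 were at least 1.5-fold lower and 0 at least 1.5-fold higher. Pclaf, which clamps onto the replication machinery, and Rrm2, which makes DNA building blocks, both stood at −1.25. Mcm6 and Mcm3, parts of the replicative helicase, stood at −1.01 and −0.77.

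Genes of oxidative phosphorylation were slightly lower as a group, with a median of −0.30 over 45 nuclear-encoded members, lower than in any of 10000 random lists of like expression. The same held in monocyte/macrophage-like and T cell-like cells, which hardly had Slc2a5, at −0.21 and −0.15. Ndufs5, a subunit of respiratory complex I, stood at −1.18 and lies within 30 Mb of Slc2a5. Ndufa4, a subunit of complex IV, stood at −0.55. Chemokines and cytokines that draw or keep lymphocytes, called chemokines below, had a median of −0.38 over 8 members, with Cxcl10 at −0.74 and Cxcl9 at −0.71, but 0.01 in female cells alone. Immunosuppressive myeloid genes had a median of 0.28 over 23 members, 6 of them at least 1.5-fold higher. The median was 0.23 over the 19 members not far below another class. The 6 higher members included the angiogenic factor gene Vegfa at 0.97 and Gpnmb, a glycoprotein of lipid-laden macrophages, at 1.40. Gpnmb is also a marker of the monocyte/macrophage class, and carry-over from that class was not tested.

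Fructose handling beyond the transporter itself moved little. The 14 measured genes of fructose and polyol handling had a median of 0.13 at percentile 96.6, with the glucose transporter gene Slc2a1 at 0.55. Glycolysis had a median of 0.04 and the pentose phosphate pathway −0.24. Homeostatic microglia genes, the signature of resting microglia, stood at 0.26. The medians for the remaining lists were −0.20 for the integrated stress response, −0.12 for NRF2 and redox genes, −0.05 for inflammatory cytokines and NF-kB targets, −0.01 for lipid synthesis and −0.0048 for the interferon-gamma response. They were 0.02 for phagocytosis and complement, 0.04 for dissociation and immediate-early genes, 0.07 for disease-associated microglia genes, 0.10 for MHC class I presentation and 0.11 for hypoxia. They were 0.12 for B cell activation, 0.18 for strain and passenger check genes, 0.22 for the type I interferon response, 0.23 for cytotoxicity and 0.24 for MHC class II presentation.

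Lymphocyte lists also stood above 0 in microglia-like cells, where free RNA, doublets and the cells' own transcripts were not separated. T cell exhaustion genes had a median of 0.37, which was 0.13 over the 12 members not far below another class, and naive T cell genes 0.43, which was 0.16 by the same rule. Regulatory T cell genes had 0.50, which turned to −0.04 at a finer clustering. Immunoglobulin constant genes had 5.19, with Igkc, the kappa light chain, at 0.334 and 13.1 CPM.

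In microglia-like cells the members at the ends of each list described, 2 highest and 2 lowest, show its spread. Genes of exhaustion included Ikzf2 at 1.204, Bhlhe40 at 0.57, Batf at −0.09 and Nr4a2 at −0.43. For the chemokine list they included the cytokine genes Il15 at 0.30 and Tnfsf13 at 0.24. The ends for the cell cycle held Hist1h2ap at 0.38 and Cenpe at −0.30. Members among immunoglobulins included Igha at 5.97, Jchain at 5.21 and Ighm at −0.32. For immunosuppression they included Mrc1 at −0.48 and Lgals3 at −0.55. The ends for naive T cells held Ly6c2 at 1.46, Bach2 at 0.80, S1pr1 at 0.03 and Igfbp4 at −0.70. Genes of oxidative phosphorylation included Uqcrh at 0.02 and Ndufa6 at 0.01. For regulatory T cells they included Ikzf2 at 1.204, Nrp1 at −0.03, Capg at −0.18 and Socs2 at −0.42.

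Single genes are ranked here and below among those with at least 100 UMIs and 50 CPM, without the groups left out of the ranking. The highest ratio among these in microglia-like cells was that of Dcstamp, which drives cell fusion, at 4.12 (3.54 and 62.3 CPM). It was followed by Csmd3 at 1.68, the transcription factor gene Zbtb20 at 1.34, Fam167b at 1.30, Marcksl1, an actin regulator gene, at 1.22 and the acute-phase gene Saa3 at 1.10. Arl4c, Arhgap15 and Mpp7, of membrane and cytoskeleton signalling, stood at 0.91, 0.90 and 0.87. The complement gene C3, the retinal reductase gene Dhrs3 and Aig1, a lipid hydrolase gene, stood at 0.84, 0.83 and 0.83.

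Lowest among the ranked genes was Cep85, a centrosome gene, at −3.14 (53.5 and 6.005 CPM). Sh3bgrl3, its neighbour on chromosome 4, stood at −1.31 (1460 and 589 CPM), and Stmn1, which takes microtubules apart, at −1.09. Ccl7, a chemokine that draws monocytes, stood at −0.93, Wfdc17 at −0.87, the interferon-induced Nmi at −0.83, Asb2 at −0.80, the scavenger receptor gene Stab1 at −0.75 and the cell cycle gene Cks1b at −0.74. Of the 12 highest, 3 genes (Fam167b, Marcksl1 and Dhrs3) lie within 30 Mb of Slc2a5. Of the 12 lowest, 4 do (Cep85, Sh3bgrl3, Ndufs5 and Stmn1).

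Monocyte/macrophage-like cells, the largest class, had higher antigen-presentation and interferon-response genes in the Glut5 KO library. The median log2 ratio was 0.83 [0.79 to 0.86] for the 29 interferon-gamma response genes, 23 of them at least 1.5-fold higher and 0 lower. Nos2, which makes nitric oxide, stood at 2.502, Upp1 at 2.48 and the chemokine gene Cxcl10 at 0.93. MHC class II presentation had a median of 0.70 [0.65 to 0.77] over 13 members, 8 at least 1.5-fold higher and 0 lower. H2-Eb1, an MHC class II chain, stood at 1.28, its master regulator gene Ciita at 1.24 and the invariant chain gene Cd74 at 1.09.

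Type I interferon response genes had a median of 0.66 over 30 members, with 18 at least 1.5-fold higher, Ifi44 at 1.11 and Bst2, the virus tether gene, at 0.19. That median was 0.89 in female cells alone and 0.31 in male cells alone. MHC class I presentation had 0.42 over 22 members, 8 at least 1.5-fold higher, with H2-Q6, whose reads overlap those of its near copies, at 1.16 and the chaperone gene Calr at −0.29. Chemokines for lymphocytes had 0.64 over 11 members, with 6 higher and 2 lower, Ccl5 at 1.01 and the B cell chemokine gene Cxcl13 at −0.70. Hypoxia genes had 0.30 over 23 members, with Egln3, an oxygen sensor gene, at 1.03 and P4ha2 at −0.73.

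Cell cycle genes were lower in these cells too, with a median of −0.72 over 32 members, 27 at least 1.5-fold lower and 0 higher. Ccnb1, the mitotic cyclin, stood at −0.99. The proliferation marker gene Mki67 was in 5.32% of 5563 thinned wildtype and 3.27% of 4869 thinned Glut5 KO cells (18 and 269 left out, medians 9184 and 7680 UMIs), or 19.5% and 12.1% without thinning. In migratory dendritic cell-like cells the thinned shares were 0% and 0.461%.

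Lymphocyte lists stood above 0 here as well, at 0.57 for cytotoxicity, 0.26 for naive T cell genes, 0.60 for regulatory T cell genes and 3.89 for immunoglobulin genes. Over the members not far below another class, the first 3 were 0.04, 0.17 and −0.09. The remaining 16 lists had medians between −0.23 and 0.22, among them dissociation and immediate-early genes, a sign of preparation, at 0.22 [0.205 to 0.25].

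In monocyte/macrophage-like cells the members at the ends of each list described, 2 highest and 2 lowest, show its spread. Genes of cytotoxicity included Gzmb at 1.58, Gzmc at 1.48, Lamp1 at −0.08 and Cx3cr1 at −0.37. For the chemokine list they included the cytokine gene Tnfsf13b at −0.32. The ends for the cell cycle held Tubb5 at −0.26, Hist1h2ap at −0.28 and Cenpf at −0.90. Genes of hypoxia included Ddit4 at 0.93 and Mxi1 at −0.17. For immunoglobulins they included Igha at 7.67, Jchain at 7.11, Ighg2b at −0.29 and Ighm at −0.56. The ends for interferon-gamma held Ifngr2 at −0.01 and Ifngr1 at −0.14. Genes of naive T cells included Satb1 at 1.17, Klf2 at −0.52 and Igfbp4 at −0.78. For type I interferon they included Ifit3b at 1.06 and Ifi27l2a at 0.14. The ends for MHC class I held H2-Q4 at 1.01 and Pdia3 at −0.23. Genes of MHC class II included Ctss at 0.13 and Cd80 at −0.09. For regulatory T cells they included Tigit at 2.28, Icos at 2.02, Itgae at −0.37 and Il10 at −0.48.

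Ranked genes with the highest ratios were Dpys, of pyrimidine breakdown, at 4.33, Dcstamp at 3.95, Gpnmb at 3.29, C3 at 1.52, Ly6a, an interferon-induced surface protein gene, at 1.31 and Zbtb20 at 1.31. The lowest were Cep85 at −3.60, Sh3bgrl3 at −1.42, the antioxidant gene Gpx3 at −1.38, the mannose receptor gene Mrc1 at −1.28, the collagen-modifying Plod1 at −1.21 and the chitinase-like Chil3 at −1.21. Cep85, Sh3bgrl3 and Plod1 lie within 30 Mb of Slc2a5. Gpnmb, Mrc1 and Chil3 are also markers of this class, and lead its cluster 5 (Gpnmb and Mrc1) or 3 (Chil3). Cluster 1 held the most wildtype cells (1763 against 1246), cluster 0 the most Glut5 KO cells (1961 against 1339), and the cycling cluster 7 held 734 and 389. Clusters 28 and 31, with 43 and 32 cells, were found only in Glut5 KO and may be that library and not a type.

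**Figure D3:**
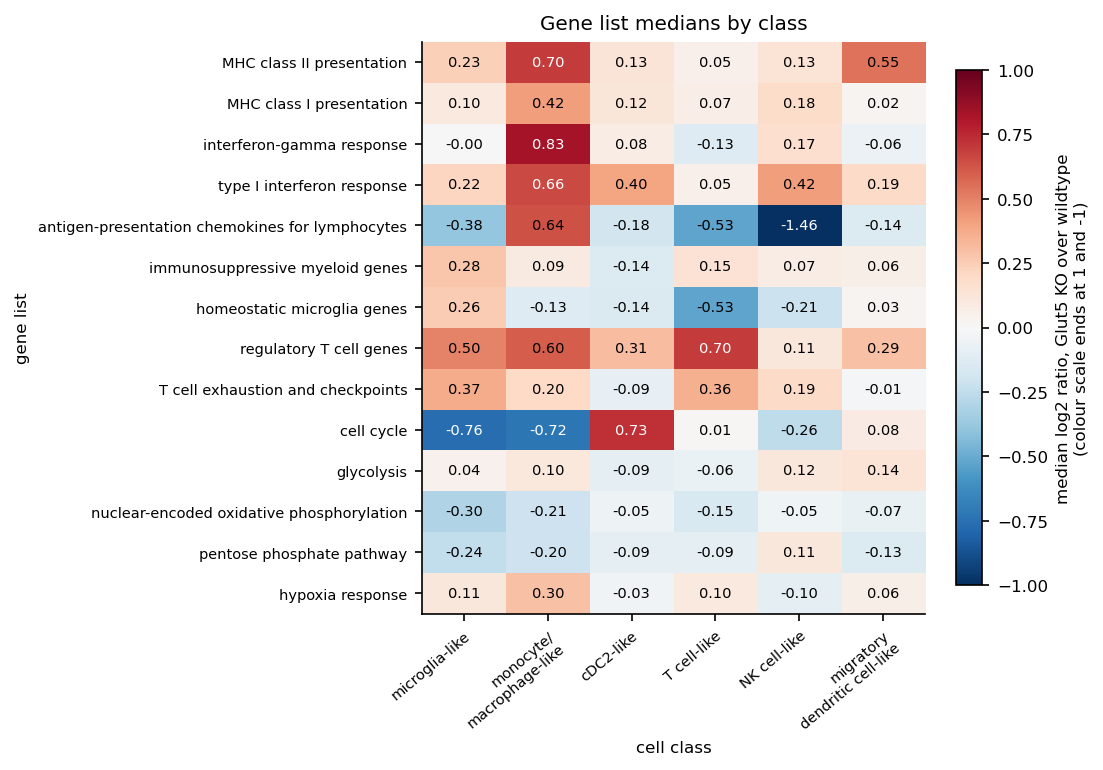
Median log2 ratio of Glut5 KO over wildtype (colour and printed value) for 14 gene lists in 6 cell classes. In monocyte/macrophage-like cells the interferon-gamma response stands at 0.83 and the cell cycle at −0.72.

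In cDC2-like cells, dendritic cells that present antigen to helper T cells, type I interferon response genes had a median of 0.40 over 30 members, 6 of them at least 1.5-fold higher. Ifi44 stood at 1.02 and Oasl1, an antiviral gene, at 0.82. Lipid and sterol synthesis had a median of −0.34 over 17 members, with Hmgcs1 and Sqle, enzymes of cholesterol synthesis, at −0.80 and −0.75. Cell cycle genes had a median of 0.73, with the spindle gene Nusap1 at 1.27, but it turned to −1.48 when each library was clustered on its own. Regulatory T cell genes stood above 0, at 0.31 [0.14 to 0.48]. Strain and passenger check genes had 0.29 [−0.04 to 0.38], an interval that includes 0, with the motor gene Kif1b, a neighbour of Slc2a5, at 1.13.

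In cDC2-like cells the members at the ends of each list described, 2 highest and 2 lowest, show its spread. Genes of the cell cycle included Cenpf at 1.26, H2afz at 0.06 and Pcna at 0.06. For lipid synthesis they included Abcg1 at 0.23 and Srebf1 at 0.22. The ends for the strain check held Errfi1 at 0.39, Eno1 at −0.29 and Vamp3 at −0.45. Genes of type I interferon included Ifi27l2a at −0.01 and Ifitm3 at −0.12. For regulatory T cells they included Il2ra at 1.64, Areg at 1.33, Tnfrsf18 at 0.05 and Batf at −0.25.

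Dpys stood at 5.61 in cDC2-like cells, Dcstamp at 3.47, the kinase gene Camk2b at 2.44, Slfn4 at 1.39, Pglyrp1, which binds bacterial wall, at 1.38 and the lipid carrier gene Apod at 1.30. Cep85 stood at −3.59, the catenin gene Ctnnd2 at −2.19, the tetraspanin gene Cd81 at −1.32, Med30 at −1.09, Sh3bgrl3 at −1.07 and the inhibitory antibody receptor gene Fcgr2b at −1.04. Dpys, Dcstamp, Ctnnd2 and Med30 lie on chromosome 15, between 30 and 60 Mb, and Cep85 and Sh3bgrl3 lie within 30 Mb of Slc2a5. The other 21 lists had medians between −0.22 and 0.24.

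T cell-like cells had higher regulatory T cell genes in Glut5 KO, with a median of 0.70 [0.56 to 0.77] over 21 members, 13 at least 1.5-fold higher and 1 lower. Areg, a tissue-repair growth factor, stood at 1.47, Lrrc32, which presents TGF-beta, at 1.18 and Ctla4 at 0.84. The costimulatory receptor gene Tnfrsf9, also among the strain and passenger check genes, stood at −0.87. Without genes within 30 Mb of Slc2a5 the list's median was 0.76 over 18 members. Exhaustion and checkpoint genes had a median of 0.36 over 23 members, with the inhibitory receptor gene Lag3 at 1.19. Integrated stress response genes had a median of −0.42 over 14 members, with the amino acid transporter gene Slc7a5 at −0.65. Naive and memory T cell genes had a median of 0.06.

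Myeloid lists were lower in T cell-like cells, in which some of these genes stand far below their level in another class. Their medians were −1.11 for phagocytosis and complement, −0.53 for homeostatic microglia genes, −0.53 for chemokines and −0.33 for disease-associated microglia genes. For inflammatory cytokines the median was −0.27 [−0.33 to 0.08], an interval that includes 0. Without members far below another class the medians, in the same order, were −0.60, −0.08, −0.53, −0.12 and 0.08. Ranked genes with the highest ratios were Igfbp7 at 2.46, Lgals7 at 2.29, the enkephalin gene Penk at 2.28, March3 at 2.02, Phactr2 at 1.69 and the phosphatase gene Dusp14 at 1.48.

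In T cell-like cells the members at the ends of each list described, 2 highest and 2 lowest, show its spread. Genes of exhaustion included Nr4a2 at 0.91 and Cd160 at −0.50. For chemokines they included Cxcl10 at −0.30, Ccl5 at −0.46 and Cxcl16 at −1.11. The ends for disease-associated microglia held Spp1 at 1.31, Timp2 at 1.09, Apoe at −1.14 and Cd68 at −1.25. Genes of homeostatic microglia included Maf at 0.63, Vsir at 0.16 and Cx3cr1 at −1.14. For inflammatory cytokines they included Ccl3 at 0.87, Nfkb1 at 0.73 and Ccl2 at −1.99. The ends for the integrated stress response held Slc3a2 at −0.02, Ddit3 at −0.04 and Aldh18a1 at −0.59. Genes of phagocytosis included Lamp2 at 0.13, Itgb2 at 0.12, Cd68 at −1.25 and C1qc at −1.56. For regulatory T cells they included Tnfrsf18 at 0.20.

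The lowest were the thyroid hormone carrier gene Ttr at −8.48, whose 623 wildtype UMIs came from 1 cell, and the monocyte genes Cd14 at −3.19, Alox5ap at −2.05 and Il1b at −1.93. Ifng, the interferon-gamma gene, stood at −1.79 and the chemokine gene Ccl1 at −1.72. In female cells alone Ttr was at 1.19, Ifng at 3.08 and Ccl1 at 0.71. Ifng was in 6.27% and 6.396% of thinned T cell-like cells. The other 18 lists had medians between −0.15 and 0.17.

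In NK cell-like cells, type I interferon response genes had a median of 0.42 over 28 members, 10 at least 1.5-fold higher, but −0.16 in female and −0.01 in male cells alone. NF-kB targets, 0.31, and B cell activation genes, 0.26, stood above 0, with the inhibitor gene Nfkbid at 1.10 and the early response gene Egr1 at 1.16. Naive and memory genes had −0.39, with the quiescence factor gene Klf2 at −1.16. Phagocytosis genes had −0.32, but −0.10 without members far below another class, and −0.10 without genes near Slc2a5. The 5 measured members of the chemokine list had −1.46 [−2.18 to −0.46], with Ccl5 at −0.48. Only 3 of the 5 were not far below another class, too few for a median of their own.

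In NK cell-like cells the members at the ends of each list described, 2 highest and 2 lowest, show its spread. Genes of B cell activation included Myc at −0.21 and H2-Aa at −0.30. For chemokines they included Cxcl10 at 0.38, and the median of that list lies below both members printed. The ends for inflammatory cytokines held Icam1 at 0.87, Tnfaip3 at 0.02 and Sod2 at −0.21. Genes of naive T cells included Tcf7 at 0.26, Ly6c2 at 0.09 and Klf3 at −0.62. For phagocytosis they included Itgax at 0.28, Lamp2 at 0.17, C1qc at −1.50 and C1qb at −1.76. The ends for type I interferon held Ifi27l2a at 1.12, Ifi44 at 0.79, Ddx58 at 0.07 and Ifitm3 at −0.46.

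The highest NK cell-like ratios among ranked genes were for Tmem176a at 2.08 and Tmem176b at 1.27, which overlap on chromosome 6 and may share reads in the counting. Ubxn11 stood at 1.56, Ly6a at 1.55 and Dhrs3 at 1.54. Ccl1 stood at −2.42, Ifitm1 at −2.06, the granzyme gene Gzme at −2.00, Ndufs5 at −1.38, Pink1, which tags damaged mitochondria, at −1.36 and the phosphatase gene Acp5 at −1.35. Of these ranked genes, Ubxn11, Dhrs3, Ndufs5 and Pink1 lie within 30 Mb of Slc2a5. Ccl1 turned to 1.198 in thinned cells and Ifitm1 to 3.30 in female cells alone. The other 20 lists had medians between −0.26 and 0.19.

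Migratory dendritic cell-like cells, which carry antigen to lymph nodes, had higher MHC class II genes in Glut5 KO, with a median of 0.55 over 13 members, 5 at least 1.5-fold higher and 0 lower. H2-Ab1 stood at 0.77. Naive T cell genes had 0.40, with the monocyte gene Ly6c2 at 2.02, and regulatory T cell genes had 0.29, with 4 members at least 1.5-fold higher, 4 lower and 4 between. This last median was −0.033 in female cells, −0.055 in male cells and −0.031 with doublets kept. Zdhhc18 stood at 1.77, the phosphatidylserine receptor gene Timd4 at 1.64, Apol7c at 1.53, Zfp36l2 at 1.48, Fcgr1 at 1.28 and Alox5ap at 1.28. The B cell chemokine gene Cxcl13 stood at −4.08, Ankrd33b at −2.14, Sh3bgrl3 at −1.23, the protease gene Ctsd at −1.18, Sf3b3 at −1.18 and the heat shock gene Hspa1b at −0.95.

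In migratory dendritic cell-like cells the members at the ends of each list described, 2 highest and 2 lowest, show its spread. Genes of naive T cells included Tcf7 at 0.59, Fam241a at −0.14 and Il7r at −0.52. For MHC class II they included H2-DMb1 at 0.75, Cd40 at 0.01 and Cd80 at −0.05. The ends for regulatory T cells held Il2ra at 0.69, Capg at 0.66, Ikzf4 at −0.59 and Tnfrsf9, also a strain and passenger check gene, at −0.91.

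Apol7c is a marker of this dendritic class, and Ankrd33b lies on chromosome 15 between 30 and 60 Mb. Zdhhc18 and Sh3bgrl3 lie within 30 Mb of Slc2a5. Cxcl13 was at 1.03 in female cells alone, Fcgr1 at −0.24 in male cells alone and Alox5ap at −0.49 with doublets kept. The other 23 lists had medians between −0.20 and 0.39.

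Mural cell or fibroblast-like cells, named by markers of cells that wrap vessels or make matrix and carry no CD45, had higher immune lists in Glut5 KO. Unlike the libraries as a whole they were almost all female by transcript, with 204 wildtype and 150 Glut5 KO cells with Xist alone against 1 and 1 with Y-linked UMIs alone. Their median depth was 15076 UMIs in wildtype and 6521.5 in Glut5 KO, and the part of depth in these differences was not tested. The medians were 1.46 for MHC class II presentation, 0.95 for the type I interferon response, 0.78 for inflammatory cytokines, 0.70 for chemokines, 0.67 for cytotoxicity (11 members, 1 of them not far below another class), 0.56 for the interferon-gamma response and 0.55 for exhaustion. They were 0.51 for homeostatic microglia genes (0.052 without members far below another class), 0.46 for B cell activation, 0.44 for phagocytosis, 0.42 for regulatory T cell genes and 0.35 for immunosuppressive genes, against −0.29 for the cell cycle. Csf1r, a receptor gene of macrophages, was at 1.21 here. With the doublet rule as first written, 9 of these lists turned below 0, MHC class II presentation among them at −0.23.

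In mural cell or fibroblast-like cells the members at the ends of each list described, 2 highest and 2 lowest, show its spread. Genes of B cell activation included Cd86 at 1.80, Npm1 at −0.11 and Mif at −0.22. For cytotoxicity they included Srgn at 1.55, Ccl5 at 0.67, Ccl3 at 0.01 and Lamp1 at −0.13. The ends for exhaustion held Bhlhe40 at 0.47, Rgs16 at 0.40 and Nr4a2 at 0.10. Members among chemokines included Cxcl16 at 1.02, Cxcl10 at 0.97 and Ccl5 at 0.67. For the cell cycle they included Hist1h2ap at 0.29, Hist1h1b at 0.19, Ccnb1 at −0.72 and Cenpe at −0.76. The ends for homeostatic microglia held Fcrls at 1.28, Bin1 at −0.13 and Tmem119 at −0.29. Genes of immunosuppression included Trem2 at 1.09, Lilrb4a at 1.04, Spp1 at −0.32 and Pvr at −0.40. For inflammatory cytokines they included Tnfaip3 at 1.40, Sod2 at −0.21 and Tnfaip2 at −0.26. The ends for interferon-gamma held Irf8 at 1.53, Tgtp2 at 1.26 and Ifngr2 at −0.21. Genes of phagocytosis included Fcgr3 at 1.19, Trem2 at 1.09, Rab7 at −0.07 and Lamp1 at −0.13. For type I interferon they included Usp18 at 1.38, Oasl1 at 0.29 and Ifitm3 at 0.11. The ends for MHC class II held Cd86 at 1.80, H2-DMb1 at 0.88 and Ctss at 0.80. Genes of regulatory T cells included Areg at 1.55, Socs2 at 0.37, Nrp1 at 0.22 and Capg at −0.06.

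Ccl12 stood at 3.18, Ccrl2 at 2.10, H2-Aa at 1.70, H2-Eb1 at 1.69, Cd74 at 1.65 and the interferon-induced Ifit3b, a near copy of Ifit3 whose reads are hard to tell apart, at 1.62. With the doublet rule as first written Ccrl2 was at −0.69 and Cd74 at −0.12. The matrix gene Sparcl1 stood at −1.95, the smooth muscle actin gene Acta2, a marker of this class, at −1.18, Cxcl9 at −1.15, Ecrg4 at −1.06, Rflnb at −0.93 and the mitotic kinase gene Plk1 at −0.89. The other 13 lists had medians between −0.17 and 0.19.

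Genes near Slc2a5 differed between the libraries more often than the pooled genes of other chromosomes in most classes. In microglia-like cells, 18 of 283 genes within 30 Mb of Slc2a5 were at least 2-fold apart, or 6.36% [3.81 to 9.87], against 86 of 8495 genes, or 1.01% [0.811 to 1.25], on other chromosomes. In T cell-like cells, which hardly had Slc2a5, the shares were 5.26% [2.55 to 9.47] and 1.37%. They were 7.05% and 2.03% in monocyte/macrophage-like, 4.29% and 0.520% in cDC2-like, and 4.72% and 0.495% in NK cell-like cells. In migratory dendritic cell-like cells, at 1.69% [0.206 to 5.99] and 0.498%, the intervals overlapped. In mural cell or fibroblast-like cells the shares were 0.461% and 1.31%. Another window, 30 to 60 Mb on chromosome 15, had a higher share in microglia-like cells, 12.1% [5.38 to 22.5]. The Slc2a5 window thus ranked 2 of 75 windows there, 4 of 81 in monocyte/macrophage-like and 1 of 57 in T cell-like cells. It ranked 1 of 57 in cDC2-like, 1 of 26 in NK cell-like and 5 of 21 in migratory dendritic cell-like cells. Only windows with at least 50 genes were ranked. This left out the higher chromosome 15 window in cDC2-like cells, at 8.51% of 47 genes, and in migratory dendritic cell-like cells, at 4% of 25. In mural cell or fibroblast-like cells it ranked 38 of 64. The genes were counted by size alone. Genes near Slc2a5 that were 2-fold apart in microglia-like cells were followed in other classes. Of those measured, 8 of 10 ran the same way in T cell-like, 5 of 5 in NK cell-like and 6 of 8 in mural cell or fibroblast-like cells. Elsewhere in the genome 32 of 46, 13 of 23 and 30 of 44 did.

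**Figure D4:**
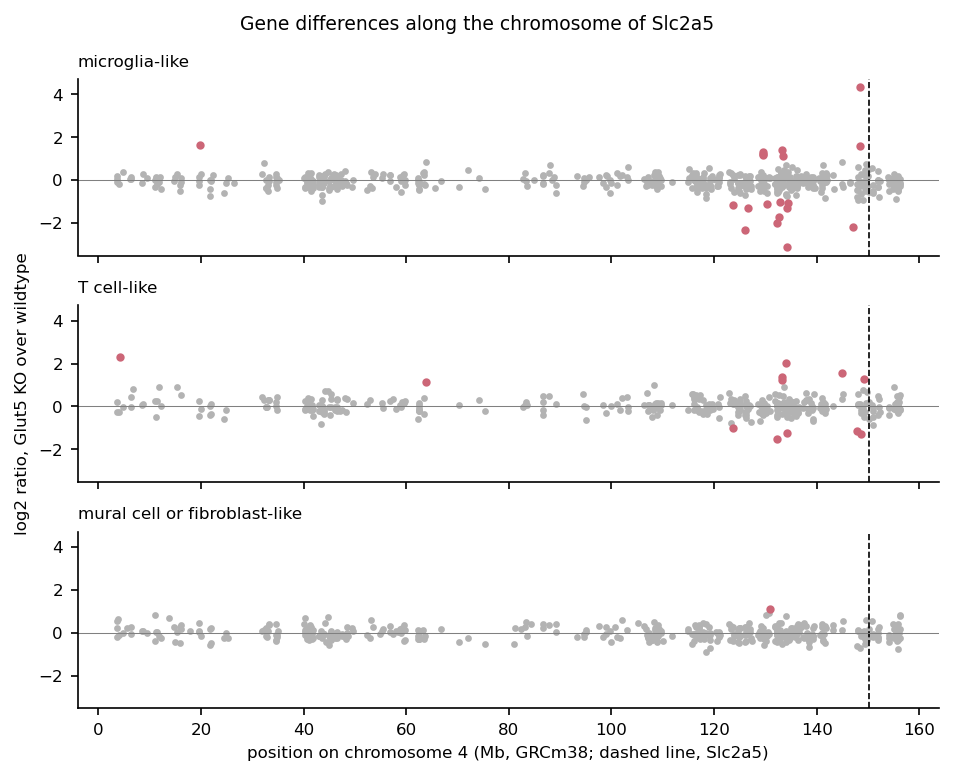
Log2 ratio of Glut5 KO over wildtype for each measured gene (points) along chromosome 4 (position in Mb) in 3 cell classes, with Slc2a5 marked. In microglia-like cells 6.36% of genes within 30 Mb were at least 2-fold apart.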

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

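All tests of explanations below were chosen only after the results they weigh had been seen.

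The change in the shares of some classes differed between female and male cells, and these differences were not tested. The log2 share ratio in female cells minus that in male cells was −0.56 for microglia-like, 0.69 for cDC2-like, 1.52 for NK cell-like, 0.67 for migratory dendritic cell-like and 1.43 for cDC1-like cells. Sex markers lay outside the comparisons of the report. Of cells with either kind of marker alone, 55.6% in wildtype and 43.3% in Glut5 KO had Y-linked UMIs, so each library held cells of both sexes. Immunoglobulin variable genes also lay outside them. In plasma cell-like cells of Glut5 KO, Ighv1-81 gave 43.0% of heavy-chain variable gene UMIs.

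Genes 2-fold apart gathered around Slc2a5, and 3 explanations were weighed. A response of the cells to the lost transporter is argued against by T cell-like cells, which hardly had Slc2a5, yet had 5.26% [2.55 to 9.47] of genes within 30 Mb 2-fold apart. A library difference is argued against by mural cell or fibroblast-like cells, at 0.461% [0.0117 to 2.54], almost all female and not shown to be of the host. DNA of another mouse strain, carried along with the targeted gene, may explain the 6.36% [3.81 to 9.87] in microglia-like cells but stays open. Mural cell or fibroblast-like cells should show it too only if they are of the host. Among those with 1 kind of sex marker, 0.488% [0.0123 to 2.69] in wildtype and 0.662% [0.0168 to 3.63] in Glut5 KO had Y-linked UMIs. Microglia-like cells stood at 39.1% and 36.7%. These values argue against hosts of both sexes as their source, so their low share was not held against linked DNA. No other origin was tested. Linkage to Slc2a5 cannot explain the higher 12.1% [5.38 to 22.5] on chromosome 15, and whether that window holds such DNA was not tested. The strain of the mice used for targeting is not given in the sources used here, so Cep85, Sh3bgrl3 and Ndufs5 cannot be read as answers to fructose.

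The Glut5 KO library had more B, plasma and T cell-like cells. Shallow barcodes are argued against by cells of at least 1000 genes, in which the lowest lower bound of the 3 log2 share ratios was 0.89. Animals of 1 sex are argued against by female and male cells taken apart, with a lowest lower bound of 1.10. Blood left in the suspension stays open, since naive and memory genes in T cell-like cells had a median of 0.059 [−0.08 to 0.14], with members both ways, while Hbb-bs (150 and 2598 UMIs), Hba-a1 (115 and 1671) and neutrophil-like cells (share ratio 5.84) were higher in Glut5 KO. The dissection, the batch and the genotype may also play a part and were not separated.

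Monocyte/macrophage-like cells of Glut5 KO had higher MHC class II and interferon-response genes. Free RNA is argued against for MHC class II, since the gain in NK-like clusters was 0.000525 of that in monocyte/macrophage-like cells (15.2 against 29040 CPM over Cd74, H2-Aa, H2-Ab1 and H2-Eb1). Another mix of clusters is argued against as the whole cause by clusters weighted equally, with a lowest median of 0.42. That weighting took MHC class II from 0.70 to 0.42 and the interferon-gamma response from 0.83 to 0.55. Part of the difference thus went with the mix of clusters. Animals of 1 sex are argued against by female and male cells, with a lowest median of 0.31. This was the type I interferon response in male cells, which stood at 0.89 in female cells. With 1 library per genotype, the batch cannot be told apart from the genotype, and Ifng itself was lower in the T cell-like cells of Glut5 KO, at −1.79, but at 3.08 in female cells alone.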

How the results depend on the processing

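Settings that use female or male cells alone, the doublet rule as first written, mixed cells kept, shallow clusters left out, clusters weighted equally or lists without genes near Slc2a5 were chosen only after the results were seen. No paired analysis was possible because there was 1 library per genotype, and no test could be made for the same reason. Of 2863 values over 198 results, 2240 stayed within the counting interval of the value reported, 576 were counted as moved and 47, in 32 results, turned direction. The 576 lay beyond that interval, except 4 medians of UMIs or genes over all deposited barcodes, which had no interval. The class shares gave 137, 33 and 10 of these, gene list medians 843, 227 and 26, and genes 1237, 308 and 11. The shallower Glut5 KO library limits shares of cells with rare transcripts such as Foxp3. The share of unnamed cells was 1.71% and 2.58%, or 0.59, and turns wherever it is given below. Values below are log2 ratios, and where not stated otherwise the cause was not tested.

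In female cells alone the shares stood at 1.55 for T cell-like, −0.38 for microglia-like, 0.54 for cDC1-like, 0.019 for migratory dendritic cell-like and −0.11 for unnamed cells. Ttr stood at 1.19, Ifng at 3.08 and Ccl1 at 0.71 in T cell-like cells, Ifitm1 at 3.30 in NK cell-like and Cxcl13 at 1.03 in migratory dendritic cell-like cells. In monocyte/macrophage-like cells MHC class II stood at 1.01, the interferon-gamma response at 1.21 and naive T cell genes at −0.0026. Chemokines stood at 0.012 and regulatory T cell genes at −0.28 in microglia-like cells, regulatory T cell genes at −0.033 in migratory dendritic cell-like and the type I interferon response at −0.16 in NK cell-like cells. In male cells alone the shares stood at 1.46 for T cell-like, 0.18 for microglia-like and −0.38 for unnamed cells. The microglia-like cell cycle stood at −0.53, Fcgr1 at −0.24 and regulatory T cell genes at −0.055 in migratory dendritic cell-like cells, and the NK cell-like type I interferon response at −0.0085.

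With the doublet rule as first written, the shares stood at 1.35 for T cell-like and −1.17 for mixed cells, and in microglia-like cells the cell cycle stood at −1.27 and regulatory T cell genes at −0.043. In mural cell or fibroblast-like cells Ccrl2 stood at −0.69, Cd74 at −0.12, MHC class II at −0.23, cytotoxicity at −1.14, chemokines at −0.92, homeostatic genes at −0.0008, immunosuppressive genes at −0.24, cytokines at −0.0064, the interferon-gamma response at −0.077, phagocytosis at −1.09 and the type I interferon response at −0.0058. With doublets kept, Alox5ap stood at −0.49 and regulatory T cell genes at −0.031 in migratory dendritic cell-like cells, and the share of unnamed cells at −0.14. Immunosuppressive genes stood at −0.062 and phagocytosis at −0.056 in mural cell or fibroblast-like cells.

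The microglia-like share stood at −0.30 at resolution 0.5 and −0.10 at a mitochondrial limit of 20%, where unnamed cells stood at −0.25. The microglia-like cell cycle stood at −0.92 at resolution 0.5, −0.94 at resolution 2, −0.90 with at least 1000 genes, −0.97 at a mitochondrial limit of 5%, −0.97 with libraries clustered separately and −0.89 without shallow clusters. With libraries clustered separately, the cDC2-like cell cycle stood at −1.48 and unnamed cells at −1.67. Without shallow clusters, the T cell-like share stood at 0.81 and unnamed cells at −0.23, and with mixed cells kept the T cell-like share was 0.68. Regulatory T cell genes in microglia-like cells stood at −0.040 at resolution 2, −0.12 without shallow clusters, −0.090 for members with at least 100 UMIs and −0.0305 without genes near Slc2a5, as fewer members were left in the last 2.

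In thinned cells Ccl1 stood at 1.198 in NK cell-like cells and Slc2a5 at 0.19 in monocyte/macrophage-like cells, where thinning left 0 Glut5 KO UMIs of Slc2a5 and the value comes from the 0.5 added to each count. In monocyte/macrophage-like cells MHC class II and the interferon-gamma response stood at 0.58 and 0.60 in thinned cells, 0.42 and 0.55 with clusters weighted equally, and 0.65 and 0.62 by the mean of per-cell CPM. The interferon-gamma response stood at 0.90 when scaled to a median of 0. Without members far below another class, MHC class II stood at 0.78 and regulatory T cell genes at −0.093.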

Other observations

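Plasma cell-like cells of Glut5 KO were mostly of the mucosal antibody type. Igha, the IgA heavy chain, was the highest heavy-chain constant gene in 82 of 122 cells (67.2%), Ighg2b in 22, Ighg2c in 11 and Ighm in 3. Ighv1-81 was the highest heavy-chain variable gene in 36 of the 120 cells with at least 3 such UMIs, which used 41 different variable genes. Among 265 B cell-like cells Ighm was the highest heavy-chain constant gene in 90, while 159 had no heavy-chain constant gene with 3 UMIs.

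Immunoglobulin transcripts in cells outside the B and plasma classes differed between the libraries. In microglia-like cells Igkc stood at 0.334 CPM in wildtype and 13.1 in Glut5 KO, Jchain at 0.200 and 8.62, and Igha at 0.134 and 10.4. The more abundant Ighm ran the other way, at 129.8 and 103.8 CPM there and 195.2 and 132.8 in monocyte/macrophage-like cells. Over all barcodes, cells and free RNA together, the globin genes had 150 and 2598 (Hbb-bs) and 115 and 1671 UMIs (Hba-a1). Ttr, a choroid plexus transcript, had 825, of which 623 came from 1 T cell-like cell, and 22721 UMIs. In Glut5 KO it stood at 234.6 CPM over all barcodes but 0.796 CPM in T cell-like cells. The collagen gene Col1a1 stood at 40.7 and 36.2 CPM.

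Among genes on chromosome 15 between 30 and 60 Mb, 12.1% were 2-fold apart in microglia-like cells, 10.1% in monocyte/macrophage-like, 8.51% in cDC2-like, 4% in migratory dendritic cell-like, 2.22% in T cell-like, 0% in NK cell-like and 1.67% in mural cell or fibroblast-like cells. Dcstamp, Dpys, Csmd3, Ctnnd2, Med30 and Ankrd33b lie there.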
